A study of Drosophila melanogaster with 4 samples.

How the data were processed

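Poly-A RNA from whole adult flies of the Oregon strain, 5 days old, had been sequenced after feeding on 1 of 2 sugars. There were 2 libraries from glucose-fed flies and 2 from galactose-fed flies. Per the labels' protocols, total RNA was extracted from whole flies with a column kit, messenger RNA was captured by its poly-A tail, and libraries were made with a kit for which no strand marking is stated. The labels give no sex and do not say whether the 2 libraries of a diet came from separate fly cultures, so p-values measure only the spread between these libraries, which may be technical.

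The authors deposited a table of raw read counts per gene for each library, whole numbers with a different total in each. Per the submitters' processing notes the tools were Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq2, with genome build BDGP6; the strand setting of the counting step is not given in the sources used here. The authors also deposited a table of their own comparison. Its 2 columns of expression signal, per the file headers a read count for each diet, equal the mean over the 2 libraries of the raw counts divided by median-of-ratios size factors, with a largest relative deviation of 5e-15. Its log2 column holds, in the deposited table, the fold change of glucose over galactose, smaller in size than the log2 ratio of the 2 means for 99.81% of genes. Its p-value columns, deposited by the authors, are a raw and an adjusted p. Values taken from it are named as the authors' deposited table, and its direction was turned to galactose against glucose where a direction is given.

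The count table lists 17628 gene identifiers, of which 17252 were named through the reference gene table. The 306 FlyBase identifiers without a name there held 4.72% of all counts, and 70 further identifiers marked as newly assembled held 0.008%. All of them stayed in the tests under their identifiers. Coordinates are from the BDGP6.54 annotation of the reference, an assembly of the same release as the build in the submitters' notes; the deposited tables hold no coordinates. Total counts were 25497099 and 23334524 in glucose replicates 1 and 2 and 23647685 and 21147212 in galactose replicates 1 and 2.

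Choices in this paragraph and the next were made before the data were examined. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM normalization, filterByExpr with the diet as group (minimum count 10, minimum total count 15), no block, and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Fold changes are galactose over glucose. Expression is given as TMM-normalized CPM, counts scaled to a common library total, as mean ± SD over the 2 libraries of a diet. Lists of genes were written from textbook Drosophila biology: 20 pathway lists and 9 lists of tissue and sex markers, with 638 of 662 members matched to an identifier. Members with an identifier that the reference table does not pair with a name were left out. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) and adjusted over the 29 lists. Camera with an estimated correlation and the rotation test fry were alternatives. Other alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, a 2-fold minimum, the replicate number as a block, and leaving out each library. DESeq2 without each library or with a block, and 2 further scalings of the list test, were added after seeing the data.

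Genes named in the text followed a written rule: those with the largest fold changes past the threshold, with a mean of at least 5 CPM and both galactose libraries on the same side of both glucose libraries. Because under 5 genes passed, the rule's fallback applied, the 10 with the smallest p in each direction, given as values that did not pass. The CPM minimum and the condition on sides were kept for the fallback, a reading of the rule made after the files were seen. The rule also takes up to 4 members per list with the smallest p and every tested member of the galactose pathway list, of which 1 is not reported here by itself. Any other gene named was chosen after its values were seen.

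With 2 libraries against 2, both galactose libraries lie above both glucose libraries for 16.7% of genes by chance, and below them for the same share. The tests were checked on simulated counts drawn from the libraries' own means, totals and dispersion, with 200 genes changed. The changed genes had means of at least 5 CPM and were not among the most abundant, so the recovered shares do not cover genes of lower level. edgeR, on 12346 genes, recovered 8% of 2-fold and 84% of 4-fold changes with 5 false calls, and DESeq2, on 12529 genes, recovered 18% and 94% with 18 false calls. In a simulation of lists, camera with the preset correlation called 1 of 29 unchanged lists as well as the shifted list. In both simulations the genes were independent of each other, unlike co-regulated genes. The recovered shares need not hold in the real libraries. There the gene AttC, with a log2 fold change of -4.26, had an edgeR adjusted p of 0.541. A lack of edgeR calls is therefore not read as a lack of large changes. Libraries were compared by Pearson correlation across genes of log2(CPM + 1). Figures were drawn with matplotlib.

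No strand marking by the kit and no strand setting of the counting are stated in the sources used here, so counts of genes that overlap another on the opposite strand are treated as uncertain. Genes with near-identical copies, among them AttA and AttB, CecA1 and CecA2, Amy-p and Amy-d, the Hsp70 genes and the lysozymes, are uncertain because the counting can split or drop their reads.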

Results

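Transcripts of whole 5-day-old Oregon flies, a standard laboratory strain of Drosophila melanogaster, were counted after feeding on glucose or on galactose, a sugar that enters glycolysis through the Leloir pathway. Each diet had 2 libraries, with total counts between 21147212 and 25497099. The series title places the comparison in a study of hormesis and inherited resistance to aging. The comparison here asks which transcripts differed between flies on the 2 sugars.

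Immune effector transcripts were the list farthest from 0. All 26 tested members of the list of antimicrobial peptides and immune effectors had a lower mean in the galactose libraries, with a median log2 fold change of -2.53, a median 5.75-fold lower level, and 23 of the 26 were lower in both galactose libraries than in both glucose libraries. Attacin C (AttC, FBgn0041579, chromosome 2R, 13393705 to 13394667), an antibacterial peptide, was at 103.3 ± 51.3 CPM (SD, n = 2) on glucose and 5.36 ± 4.92 on galactose, a log2 fold change of -4.26 ± 0.75 (SE). Bomanin BomS1 (FBgn0034329, 2R, 18383949 to 18384378), a short secreted peptide induced by infection, was at 113.0 ± 75.3 CPM on glucose and 11.6 ± 4.90 on galactose, and the peptidoglycan recognition protein PGRP-SB1 (FBgn0043578, 3L, 16727299 to 16727989) was at 52.7 ± 17.6 and 9.04 ± 3.25. AttB (FBgn0041581, 2R, 14749223 to 14750165) was at 37.8 ± 23.4 and 2.50 ± 0.74 CPM, a value that is uncertain because AttA is a near-identical copy. Members with fold changes near 0 were Def, Drsl2 and PGRP-SC2, with log2 values of -0.09, -0.08 and -0.06, chosen after their values were seen.

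The list passed camera with the preset correlation (adjusted p = 1.29e-35 over 29 lists), and not with an estimated one (adjusted p = 0.732 with an estimated correlation). Camera's unadjusted p with an estimated correlation was 0.0599 for this list, 0.266 for Turandot stress peptides and 0.388 for cytosolic ribosomal proteins. Adjustment gave each of the 13 lists past the preset test the same 0.732, so that value does not rank them. With 2 residual degrees of freedom, failing this test does not show that a list was unchanged. By edgeR's quasi-likelihood test 0 members of the immune list passed over all genes tested (adjusted p = 0.541 for each of the 4 genes above). Adjusted over the list alone 20 passed, all lower. DESeq2 called 12 members over all genes, all lower. Without each library in turn the list's median was between -3.17 and -1.996. When the 4 libraries were split against the diets, glucose replicate 2 and galactose replicate 1 against the others, the same list had a median of 0.95 and adjusted p = 1.29e-11, so a small p of the preset test was not particular to the diet.

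**Figure D1:**
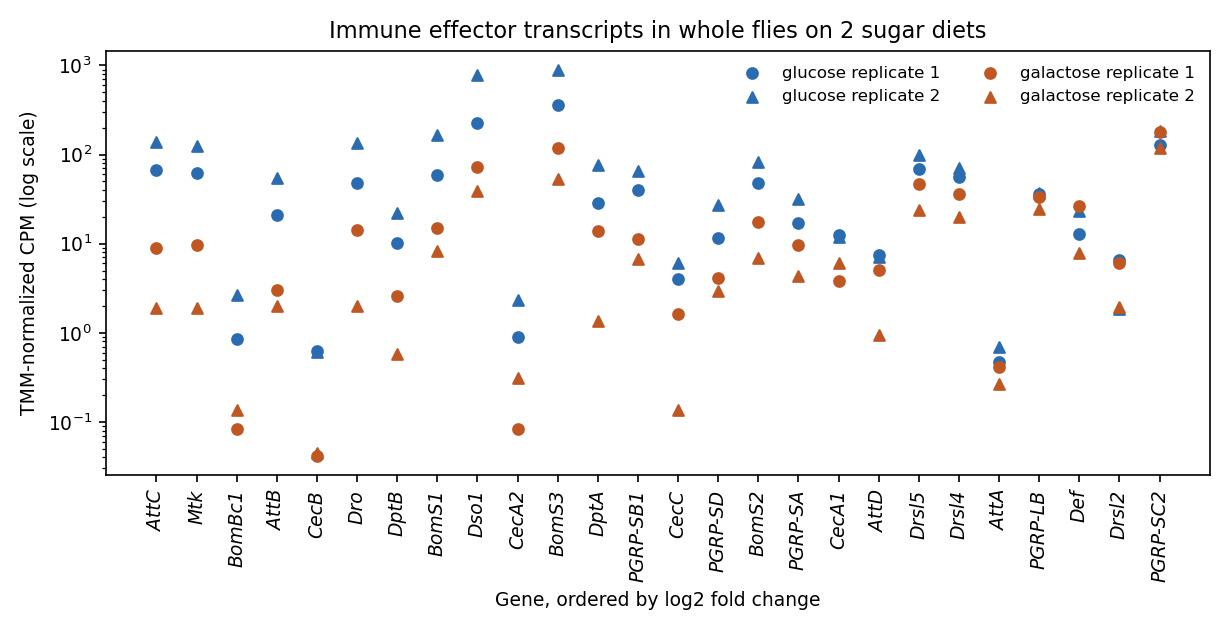
TMM-normalized CPM (log axis) of the 26 tested immune effector genes in each of the 4 libraries, blue for glucose and orange for galactose, circles for replicate 1 and triangles for replicate 2, with genes ordered by log2 fold change. For 23 of the 26 genes both orange points lie below both blue points.

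Over all 12529 genes tested, edgeR's quasi-likelihood test called 0 genes at an adjusted p of 0.05, with a smallest adjusted p of 0.541. At an unadjusted p under 0.05 there were 1033 genes, 386 higher and 647 lower on galactose, where chance alone gives 626. Splitting the libraries by replicate number instead of diet gave 931 such genes and also 0 called. The remaining split, glucose replicate 2 and galactose replicate 1 against the others, gave 112, under the 626, and 0 called. limma-voom called 0 for the diets. DESeq2 called 88 genes, 13 higher and 75 lower on galactose. The authors' deposited table holds 87 genes at an adjusted p under 0.05, 12 higher and 75 lower on galactose, of which 85 were among the DESeq2 calls in the same direction and 0 among the edgeR calls. Both galactose libraries lay below both glucose libraries for 2931 genes (23.4%) and above them for 2358 (18.8%), against 16.7% by chance for each. The split of the unadjusted genes depended on scaling: 62.6% were lower with TMM, 53.3% with median-of-ratios scaling and 78.5% with upper-quartile scaling, the last of which moved the median log2 fold change of all genes by -0.111. Counts of calls depended on single libraries. edgeR called 549 genes without glucose replicate 1 and 147 without glucose replicate 2, and 0 without either galactose library. DESeq2 called 328 without glucose replicate 1, 17 without glucose replicate 2, 48 without galactose replicate 1 and 22 without galactose replicate 2.

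The 10 genes with the smallest p and lower values on galactose, none past the edgeR threshold, included AttB, PGRP-SB1 and BomS1, given above. Listericin, an antibacterial peptide (FBgn0033593, 2R, 11241745 to 11242194), was at 84.2 ± 35.6 CPM on glucose and 17.1 ± 3.50 on galactose. GNBP-like3 (FBgn0034511) was at 148.1 ± 109.1 and 14.4 ± 5.21. BomT1 (FBgn0262838), another Bomanin, was at 13.4 ± 7.68 and 1.30 ± 0.51. The cytochrome P450 gene Cyp6w1 (FBgn0033065, 2R, 6173684 to 6176195) was at 103.1 ± 19.9 and 33.1 ± 1.40, a log2 fold change of -1.64 ± 0.27 (SE). The odorant-binding protein gene Obp56d (FBgn0034470) was at 202.2 ± 33.9 and 68.4 ± 4.55 CPM, ejaculatory bulb protein EbpIII (FBgn0011695) at 827.4 ± 155.8 and 298.9 ± 4.66, and CG17571 (FBgn0259998) at 189.7 ± 28.2 and 69.0 ± 1.29. By edgeR's quasi-likelihood test the adjusted p was 0.541 for each, while DESeq2 called these 7 genes with adjusted p between 4.63e-08 and 0.00818.

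The 10 genes with the smallest p and higher values on galactose also did not pass the edgeR threshold. The poly(A) polymerase gene wisp (FBgn0260780, X, 11893943 to 11899920), which acts in oocytes, was at 187.6 ± 4.23 CPM on glucose and 426.4 ± 88.1 on galactose, a log2 fold change of 1.19 ± 0.26 (SE). Marf1 (FBgn0039972) was at 135.4 ± 23.6 and 301.1 ± 34.5, the germline TRIM-NHL gene mei-P26 (FBgn0026206) at 57.1 ± 7.91 and 120.0 ± 15.7, and pumilio (pum, FBgn0003165), a translational repressor, at 110.5 ± 6.80 and 215.4 ± 33.1. The co-repressor gene Smr (FBgn0265523) was at 89.6 ± 1.92 and 201.5 ± 57.4 CPM. Acf (FBgn0027620), a chromatin remodelling factor, was at 61.5 ± 2.92 and 121.7 ± 12.8. The Notch ligand gene Delta (FBgn0000463) was at 27.1 ± 2.96 and 60.6 ± 16.5, Mov10 (FBgn0034187) at 30.6 ± 0.94 and 70.0 ± 23.5, CG32767 (FBgn0052767) at 43.8 ± 4.94 and 98.8 ± 29.5, and FBgn0086899, unnamed in the reference table, at 71.9 ± 11.9 and 155.0 ± 39.3. The edgeR adjusted p was between 0.541 and 0.582 for these 10 genes. DESeq2 called wisp and Marf1, with adjusted p of 0.0409 and 0.046. The genes of the 2 directions also differed in length. Apart from FBgn0086899, for which no length was at hand, the higher genes had from 3474 (Mov10) to 23228 (mei-P26) annotated exonic bases. The 10 lower genes had from 361 (BomS1) to 2392 (Cyp6w1). Whether the differences followed transcript length, for these genes or for the lists, was not tested.

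Genes of galactose use, the Leloir pathway, did not pass the test as a list. The median log2 fold change of the 9 tested members was -0.34, 8 were negative, and camera gave an adjusted p of 0.111 over the lists, with 0 members called over all genes or adjusted over the list alone. Galactokinase (Galk, FBgn0263199, 3L, 8982212 to 8986091) was at 124.1 ± 3.33 CPM on glucose and 107.5 ± 17.3 on galactose, and the uridylyltransferase gene Galt (FBgn0263200, 2L, 6666264 to 6668033) at 105.0 ± 18.8 and 67.6 ± 18.0. UGP (FBgn0035978) was at 214.3 ± 21.1 and 238.8 ± 19.4 CPM and Pgm1 (FBgn0003076) at 388.5 ± 119.6 and 310.0 ± 48.0. The members known by a CG number were CG10467 at 35.1 ± 1.49 and 33.2 ± 4.37, CG32444 at 80.7 ± 12.2 and 61.4 ± 11.0, CG10996 at 5.92 ± 4.91 and 3.93 ± 0.73, and CG4988 at 16.0 ± 7.23 and 8.88 ± 2.83. The edgeR adjusted p lay between 0.615 and 0.923 over these 8 genes. Exons of Galk, UGP and CG32444 overlap genes on the opposite strand over 25.1%, 21.4% and 28.6% of their bases, so their counts are uncertain. The list's adjusted p was 0.732 with an estimated correlation. Without galactose replicate 1 the list passed with the preset correlation (adjusted p = 0.0445, median -0.56), while without galactose replicate 2 the median was -0.216 (0.41) and without glucose replicate 2 it was -0.224 (0.219).

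**Figure D2:**
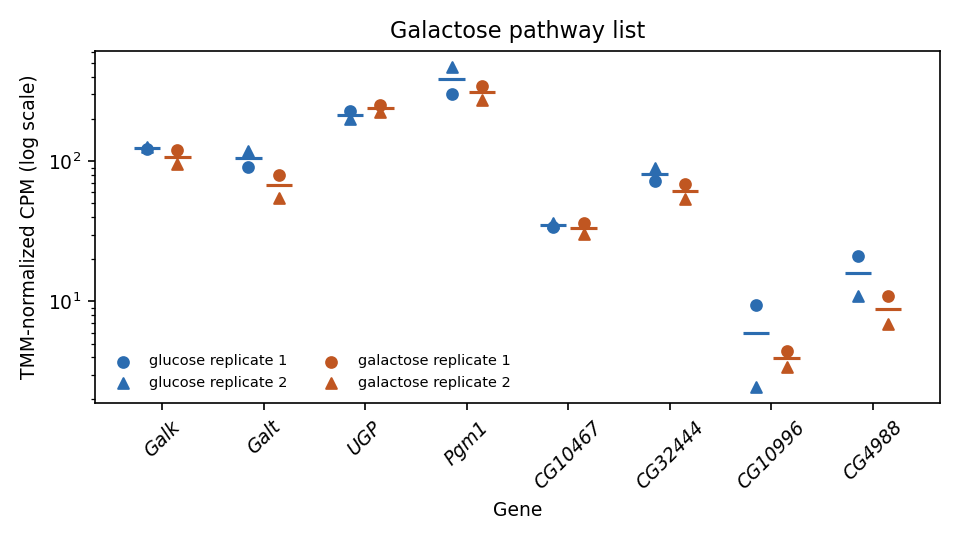
TMM-normalized CPM (log axis) of 8 genes of the galactose pathway list in each library, blue for glucose and orange for galactose, with a bar at the mean of the 2 libraries of a diet. Galt was at a mean of 105.0 CPM on glucose and 67.6 on galactose, and none of these 8 genes passed the edgeR test.

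Lists of digestion, carbohydrate and energy metabolism also had lower medians on galactose. Sugar digestion enzymes had a median log2 fold change of -0.66 over 13 members (camera adjusted p = 7.36e-05), with 11 negative. The maltase gene Mal-A8 (FBgn0033297) was at 130.3 ± 38.1 CPM on glucose and 46.0 ± 6.63 on galactose, and tobi (FBgn0261575), a glucosidase gene under insulin and glucagon-like control, at 92.1 ± 11.1 and 39.8 ± 21.9. The citric acid cycle list had a median of -0.40 with 15 of 15 members negative (adjusted p = 0.000398). Its succinate dehydrogenase gene SdhB (FBgn0014028) was at 334.5 ± 38.8 and 209.4 ± 14.5. Gluconeogenesis, glycogen and trehalose had a median of -0.36 over 10 members (adjusted p = 0.00789). Pepck2 (FBgn0034356) was at 48.3 ± 10.8 and 23.0 ± 1.70 and the trehalose synthase gene Tps1 (FBgn0027560) at 1208 ± 147.6 and 653.9 ± 159.5. Fatty acid synthesis had a median of -0.26 over 13 members (adjusted p = 0.0412), with FASN2 (FBgn0042627) at 533.3 ± 219.7 and 209.8 ± 36.3. For all 4 lists the adjusted p was 0.732 with an estimated correlation, edgeR called 0 members over all genes, and adjusted over the list alone it called 1 member of the sugar digestion list and 0 of the others. Without glucose replicate 2 none of the 4 lists passed, with adjusted p of 0.0615, 0.219, 0.258 and 0.431 in the order above and medians of -0.139, -0.213, -0.317 and -0.038. The sugar digestion median was -1.25 without galactose replicate 1 and -1.04 without glucose replicate 1, and the fatty acid median was -0.44 without glucose replicate 1. Fatty acid synthesis also did not pass without galactose replicate 1 (0.0882) or with median-of-ratios scaling (0.0564).

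Further lists lower on galactose were detoxification, translation, muscle, eye and stress peptides. Detoxification cytochromes P450 had a median log2 fold change of -0.46 over 44 members, 36 negative (adjusted p = 3.72e-06), with Cyp6a8 (FBgn0013772) at 64.4 ± 9.78 CPM on glucose and 27.4 ± 5.27 on galactose. Cytosolic ribosomal proteins had 56 of 57 members negative but a narrow shift, with quartiles of -0.43 and -0.32 (adjusted p = 7.52e-08). RpS26 (FBgn0261597) was at 3517 ± 284.4 and 2496 ± 312.6. Muscle genes had a median of -0.62 with 22 of 23 negative (adjusted p = 1.89e-08), among them the actin gene Act79B (FBgn0000045) at 1068 ± 323.8 and 561.2 ± 130.4. Photoreceptor genes had a median of -0.72 over 23 members, 17 negative (adjusted p = 8.14e-07). The phototransduction channel gene trpl (FBgn0005614) was at 164.8 ± 26.6 and 74.5 ± 20.9. The 4 tested Turandot stress peptides had a median of -1.27 (adjusted p = 0.00789), with TotC (FBgn0044812) at 104.4 ± 40.0 and 41.7 ± 35.2. Only 2 of the 4 were lower in both galactose libraries, and the list's median deviation was 0.175 in glucose replicate 2 and 0.184 in galactose replicate 1. For each of these 5 lists the adjusted p was 0.732 with an estimated correlation, 0 members were called over all genes by edgeR, and adjusted over the list alone 1 P450 member and 1 member of the eye list, the cuticle protein gene Cpr72Ec, were. The Turandot list did not pass without galactose replicate 2 (adjusted p = 0.0852, median -0.585) or glucose replicate 1 (0.0589, median -0.631), and its median was -2.656 without galactose replicate 1. Leaving out galactose replicate 2 gave medians nearer 0, of -0.37 for the eye, -0.41 for muscle, -0.27 for P450 and -0.19 for ribosomal genes. Leaving out galactose replicate 1 gave medians farther from 0, of -1.02 for the eye, -0.94 for muscle, -0.84 for P450 and -0.68 for ribosomal genes.

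Lists with higher medians on galactose were the female germline, chromatin modifiers and neurons. Female germline markers had a median log2 fold change of 0.57 over 17 members, 16 positive (adjusted p = 1.1e-05), with the piRNA pathway gene AGO3 (FBgn0250816) at 40.0 ± 24.0 CPM on glucose and 93.9 ± 8.35 on galactose and staufen (stau, FBgn0003520) at 74.1 ± 9.69 and 123.6 ± 28.1. Chromatin modifiers had a median of 0.49 over 49 members, 45 positive (adjusted p = 6.95e-08). The histone methyltransferase gene Set8 (FBgn0011474) was at 52.9 ± 6.47 and 97.4 ± 25.2, the Polycomb group gene Pcl (FBgn0003044) at 78.8 ± 15.02 and 143.4 ± 37.8, and trithorax (trx, FBgn0003862) at 28.7 ± 1.11 and 47.1 ± 7.92. Of the 49 chromatin modifiers 14 were higher in both galactose libraries than in both glucose libraries, and the list's median deviation was higher in glucose replicate 2 (0.087) than in galactose replicate 1 (-0.054), so the libraries did not separate by diet. The female germline and chromatin lists were each highest in galactose replicate 2, at 0.60 and 0.52. Neuronal genes had a median of 0.37 over 17 members (adjusted p = 0.00635), with the synaptic gene unc-13 (FBgn0025726) at 43.0 ± 20.5 and 77.6 ± 13.01, a count that is uncertain because 28.4% of its exonic bases are shared with other annotated features, some of them on the opposite strand. Of the 17 neuronal genes 5 were higher in both galactose libraries, and the list's median deviation was 0.25 in glucose replicate 1 and -0.19 in galactose replicate 2. For all 3 lists the adjusted p was 0.732 with an estimated correlation and edgeR called 0 members, over all genes or adjusted over the list alone. Chromatin modifiers did not pass without glucose replicate 1 (adjusted p = 0.149, median 0.13) and had a median of 0.09 without galactose replicate 2 and of 0.85 without glucose replicate 2. The germline median was 0.29 without galactose replicate 2. The neuron median was -0.09 without glucose replicate 2 and -0.23 without galactose replicate 1.

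**Figure D3:**
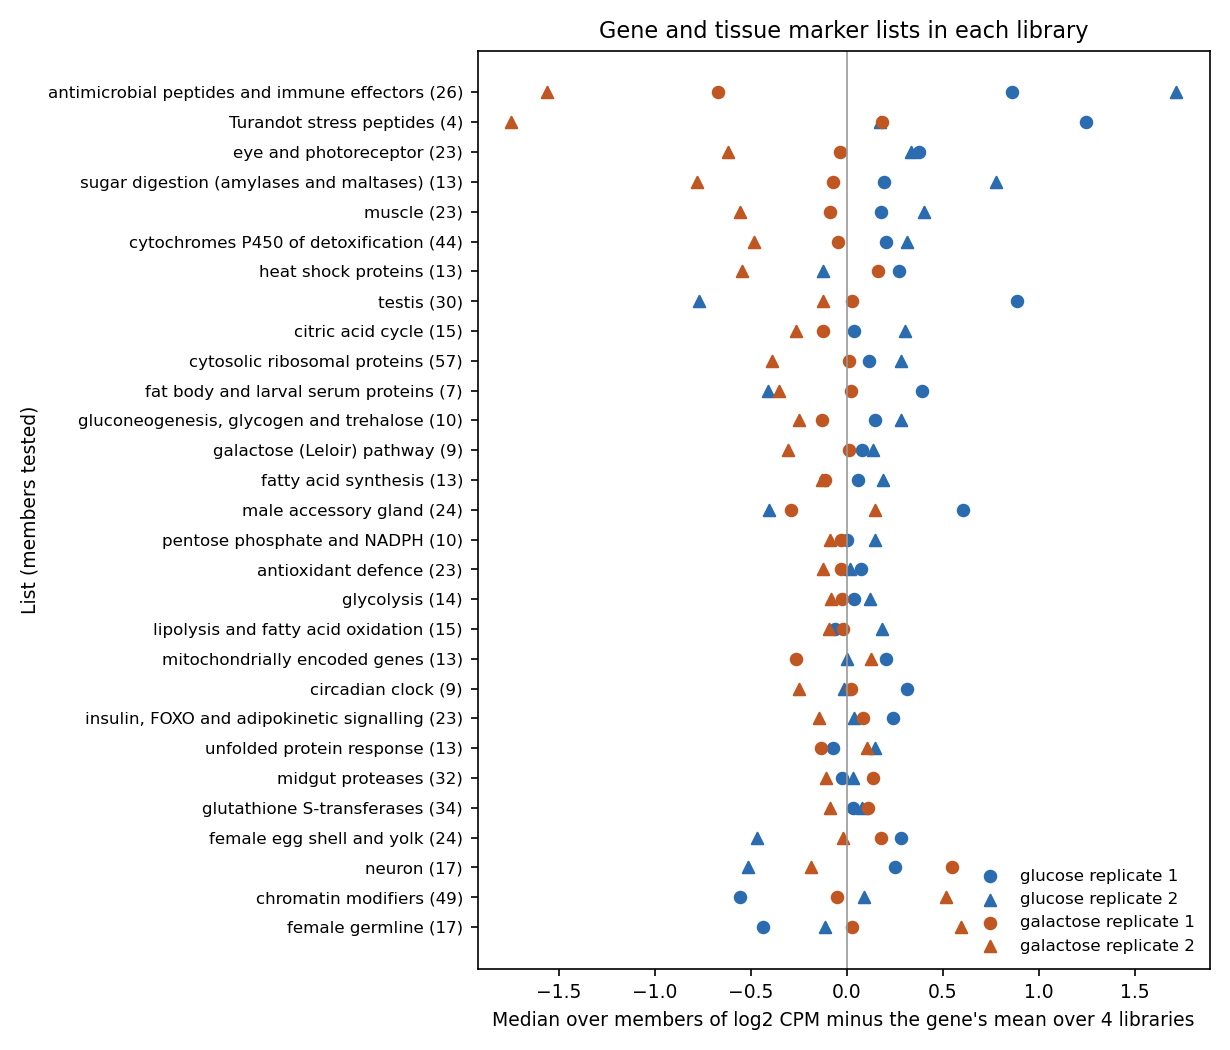
Median over the tested members of each list of a gene's log2 CPM minus its mean over the 4 libraries, per library, blue for glucose and orange for galactose, circles for replicate 1 and triangles for replicate 2; the number of tested members is in parentheses. Immune effectors lie at 0.86 and 1.72 in the glucose libraries and at -0.67 and -1.56 in the galactose libraries, while the testis list separates glucose replicate 1 (0.89) from glucose replicate 2 (-0.77).

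The other 16 lists, the Leloir pathway among them, did not pass camera with all 4 libraries. Median log2 fold changes were -0.44 for heat shock proteins (adjusted p = 0.133), -0.42 for testis (0.111), -0.39 for fat body and larval serum proteins (0.155), -0.22 for male accessory gland (0.215), -0.17 for pentose phosphate and NADPH (0.216), -0.14 for antioxidant defence (0.582) and -0.14 for glycolysis (0.264). They were -0.12 for lipolysis and fatty acid oxidation (0.397), -0.10 for mitochondrially encoded genes (0.301), -0.06 for the circadian clock (0.533) and -0.01 for insulin, FOXO and adipokinetic signalling (0.526), the last of which was 0.04 with median-of-ratios scaling. The unfolded protein response was at 0.003 (0.934), midgut proteases at 0.03 (0.344), glutathione S-transferases at 0.04 (0.902) and egg shell and yolk at 0.09 (0.179), and each of these 4 was below 0 with upper-quartile scaling. Some of these lists passed with the preset correlation when 1 library was left out. An estimated correlation was used only with all 4 libraries, where 0 lists passed. Egg shell and yolk and male accessory gland each had a camera adjusted p of 0.813 in that test. Without glucose replicate 1 egg shell and yolk was at 0.53 (6.85e-05) and male accessory gland at 0.40 (0.0304), while fat body was at 0.20 and did not pass (0.965). Without glucose replicate 2 heat shock proteins were at -0.76 (0.0219), fat body at -0.78 (0.00285) and male accessory gland at -0.63 (8.19e-06). Without galactose replicate 1 heat shock proteins were at -0.96 (0.00791). Without galactose replicate 2 egg shell and yolk was at 0.19 (0.00835), midgut proteases at 0.15 (0.00879), mitochondrially encoded genes at -0.29 (0.00527) and male accessory gland at -0.44 (0.000534). Within the heat shock list, Hsp68 (FBgn0001230) was at 46.7 ± 0.93 CPM on glucose and 20.1 ± 0.42 on galactose. The gene l(2)efl (FBgn0011296) was at 218.9 ± 92.7 and 78.4 ± 17.9, and both genes passed adjusted over the list alone. Hsp26 (FBgn0001225) went the other way, at 499.8 ± 229.4 and 766.1 ± 51.6. Of the list's members 3 were higher and 3 lower in both galactose libraries than in both glucose libraries. The midgut protease genes Jon66Cii (FBgn0035887) and Jon66Ci (FBgn0035886) were at 6.55 ± 5.40 and 74.6 ± 61.1 CPM on glucose and at 30.4 ± 0.19 and 253.5 ± 80.4 on galactose. DESeq2 called both, with adjusted p of 0.00225 and 0.0382.

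The glucose libraries were less alike than some pairs of libraries from different diets. Across genes, which are not independent replicates, the Pearson correlation of log2(CPM + 1) was 0.9814 between the glucose libraries and 0.9915 between the galactose libraries, and between diets it ran from 0.9789 to 0.9899, the latter for glucose replicate 1 and galactose replicate 1. Testis genes had a median log2 ratio of -1.68 for glucose replicate 2 over glucose replicate 1 and -0.13 for galactose replicate 2 over 1, and accessory gland genes of -0.91 and 0.40. The testis tubulin gene betaTub85D (FBgn0003889) was at 344.4 CPM in glucose replicate 1, 218.2 in glucose replicate 2, and 179.6 and 194.7 in the galactose libraries. Without glucose replicate 1 the testis median between diets was 0.73 (camera adjusted p = 6.85e-05) and without glucose replicate 2 it was -0.91 (6.48e-14), against -0.42 with all 4 libraries. These p use the preset correlation; for testis the correlation was estimated at 0.84 with all 4 libraries, and the adjusted p was 0.813 with an estimated correlation.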

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

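The fits without single libraries have 1 library in an arm, which is assumed to vary like the others. Their spread is estimated from the 2 libraries of the other diet alone. Without a glucose library that was the galactose pair, correlated at 0.9915. Without a galactose library it was the glucose pair, correlated at 0.9814. DESeq2 without single libraries or with a block, and the list test with upper-quartile scaling or without reproductive genes, were chosen after seeing the data. edgeR called 0 genes with each other scaling, filter and fold minimum, with limma-voom and with the replicate block, and DESeq2 called 88 (13 higher, 75 lower). Without single libraries edgeR called 0 to 549 genes, 0 to 199 higher and 0 to 350 lower; of the 549 without glucose replicate 1, 87 were among the 88 DESeq2 calls, and of the 147 without glucose replicate 2, 52 were. DESeq2 called 17 to 328 genes, 1 to 127 higher and 13 to 201 lower. The labels do not say that replicate numbers pair the libraries; deviations of same-numbered libraries correlated at 0.217 across genes, and with the replicate number as a block DESeq2 called 131 genes, 32 of them higher, 80 shared with the 88, while 13 lists passed as before. With an estimated correlation or with fry 0 of the 13 lists passed, the smallest adjusted p being 0.732 and 0.473. The overlap with the authors' deposited table was 0 with edgeR calls and 85 with DESeq2 calls. The cause of these differences was not tested. In the main edgeR fit no named gene passed, so a named gene that kept its side of the threshold again did not pass, and none could be lost. For named genes, 1193 of 1267 alternative values kept their direction and side of the threshold, 68 passed it and 6 reversed; for lists, 246 of 319 did, 35 no longer passed, 11 newly passed and 27 reversed.

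Medians of log2 fold change reversed as follows, and the cause was not tested. Without single libraries, where the lowest and highest values follow, the circadian clock ran from -0.465 to 0.204 (0.077 without galactose replicate 2), fat body from -0.777 to 0.196, egg shell and yolk from -0.177 to 0.531 (-0.089 without galactose replicate 1), glutathione S-transferases from -0.143 to 0.073 (-0.078 and -0.048 without glucose replicates 1 and 2) and heat shock proteins from -0.96 to 0.11 (0.047 without galactose replicate 2). Insulin signalling ran from -0.294 to 0.007, lipolysis from -0.22 to 0.024, male accessory gland from -0.629 to 0.399, midgut proteases from -0.089 to 0.148 (-0.047 without glucose replicate 1), mitochondrially encoded genes from -0.286 to 0.088 (0.02 without galactose replicate 1), neurons from -0.233 to 0.761 (-0.087 without glucose replicate 2), testis from -0.91 to 0.733 and the unfolded protein response from -0.15 to 0.105 (-0.149 without glucose replicate 1). With upper-quartile scaling egg shell and yolk was at -0.02, glutathione S-transferases at -0.05, midgut proteases at -0.083 and the unfolded protein response at -0.103; with median-of-ratios scaling insulin signalling was at 0.036. Single genes that reversed without 1 library were Pgm1 (-0.611 to 0.034, the last without glucose replicate 2), CG10996 (-1.25 to 0.677), Mst57Da (-1.079 to 0.008) and TotX (-1.084 to 0.005, these 3 highest without glucose replicate 1), CG10467 (-0.29 to 0.053) and Ire1 (-0.031 to 0.46), these last reversed without galactose replicate 2.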

Other observations

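The tests on the sex ratio and on ovary RNA were chosen only after the result was seen; the other tests were fixed before any list value was computed, though single immune and germline genes had by then been seen in each library. Cuticle genes, chosen after their values were seen and not tested as a list, went both ways. Of 14 tested Osiris genes, 7 were higher in both galactose libraries than in both glucose libraries, 4 were lower, and DESeq2 called 4. Over all genes 18.8% were higher and 23.4% lower, and DESeq2 called 88 of 12844. Osiris levels were low, and the called gene Osi18 was at 0.08 and 0 CPM on glucose and 1.29 and 1.35 on galactose. Osi7, also called, was at 0.74 and 0.14 on glucose and 7.60 and 0.72 on galactose, so its diets overlapped. Of 16 tested Tweedle genes, which encode cuticle proteins, 5 were higher in both, 1 was lower and DESeq2 called 1. The called Tweedle gene, TwdlF (FBgn0037224), was at 0.19 and 0 CPM in the glucose libraries and 6.18 and 5.12 in the galactose libraries. DESeq2 called other cuticle genes lower on galactose, namely Cpr72Ec, Cpr47Ef, Lcp1 and Cpr65Au, with log2 fold changes of -2.71, -2.32, -2.06 and -1.30.

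Splitting the 4 libraries into pairs in each of the 3 possible ways, the diets gave 88 genes by DESeq2 and at most 6 were given by another split. edgeR called 0 genes in each split. At an unadjusted p under 0.05 it gave 1033 for the diets, 931 for the split by replicate number and 112 for the remaining split. For lists past camera the diets gave 13 and the highest other split also gave 13. With 3 splits no share under 0.05 can be reached.

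The first pattern is the lower level of immune effectors on galactose. Less fat body RNA in those libraries, the tissue that makes many of these peptides, would lower fat body markers as much, but their median was -0.391, with quartiles of -0.868 and -0.051, against -2.525 for the immune list. The fat body median moved with single libraries, to -0.777 without glucose replicate 2 and 0.196 without glucose replicate 1. The immune medians in those fits were -1.996 and -2.902. Only 7 members of the fat body list were tested, and some encode larval serum proteins. Lsp1beta was at 33.7 CPM in glucose replicate 1 and 5.65 in glucose replicate 2, and Lsp1gamma ran from 1.44 to 4.77. The list may therefore not follow the fat body share of adults, so it cannot decide this explanation. A single glucose library with raised immune transcripts would leave little difference without it, but without glucose replicate 2 the median was -1.996, and it stayed below -0.5 without each library. A difference in infection or microbial load between fly cultures stays open, since the labels do not describe separate cultures. Less fat body RNA and the diet itself also stay open, and none of these can be preferred from these data.

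The second pattern is that libraries of 1 diet differ from each other. The totals were close, and thinning to 1 total left the lowest correlation within a diet, that of the glucose libraries, at 0.9813, against 0.9814 before. The low correlation thus remained at equal totals. Because the totals were so close, thinning could hardly have changed it, so this test does not decide about depth. A sex ratio with fewer males and more females in glucose replicate 2 would go with its testis median of -1.678. Its accessory gland median of -0.908 and germline median of 0.341 would go with it too. Egg shell and yolk genes should then rise, but their median was -0.614 with an upper quartile of -0.189. From glucose replicate 1 to 2 the yolk gene Yp1 rose from 1894 to 2455 CPM and Yp2 from 8950 to 10740. The egg shell gene Cp19 fell from 1262 to 358. Most members of the list thus fell, as its upper quartile below 0 shows, while Yp1 and Yp2 rose. The count of Yp1 is uncertain, since 54.3% of its exonic bases overlap a gene on the opposite strand. Testis, accessory gland and germline medians went with this sex ratio and most egg shell and yolk genes did not, so it was not decided. A different share of female germline RNA cannot be told apart from other causes: germline medians of replicate 2 over 1 were 0.341 on glucose and 0.324 on galactose, while egg shell medians were -0.614 and -0.158. The labels name no biological difference within these pairs.

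The third pattern is the higher female germline list on galactose. More ovary RNA with its follicle cells would raise egg shell genes alike. With all 4 libraries their median was 0.085 with an upper quartile of 0.314, below the germline's lower quartile of 0.488, but without glucose replicate 1 the egg shell median was 0.531 and the germline median 0.402, and without galactose replicate 2 they were 0.192 and 0.285. A larger share of ovary RNA therefore cannot be told apart from an effect of the diet on these transcripts, because the answer turns on 1 library. A larger share of germline cells alone stays open and untested.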
